A study of Mus musculus with 16 samples.

How the data were processed

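Circular RNAs (circRNAs) were measured by sequencing in hearts of male C57BL/6 mice. Per the labels' protocols, ischaemia was made by tying the left anterior descending coronary artery for 30 min, and hearts were taken after reperfusion for 1 week. The design names 4 groups of 8 mice: Sham, the injury model (MIRI), MIRI+AICAR and MIRI+Compound C. There were 3 Sham, 3 MIRI, 5 MIRI+AICAR and 5 MIRI+Compound C libraries, 16 in all. The labels do not say how the 32 mice became 16 libraries, nor that replicates were separate mice, so p-values measure the spread between these samples, which may be technical. The label gives cardiac muscle cell as the cell type, but no sort or isolation is described.

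Per the labels' protocols, ribosomal RNA was depleted, linear RNA was digested with RNase R, and stranded libraries were made with the dUTP method and sequenced as DNA nanoballs. Per the submitters' processing notes, back-splice junctions were called with CIRI, whose version and read minimum are not given in the sources used here. The deposited table holds back-splice counts for 68854 circRNAs per library, as the authors made them, with no further normalisation. No count of 1 occurs and the smallest above 0 is 2, so a circRNA listed at 0 can have had 1 read. The table lists 28473 circRNAs at 0 in all libraries. Per the submitters' processing notes the genome build was mm9, but 88.9% of exonic circRNA starts and 88.8% of ends lie on exon boundaries of GENCODE M21 on GRCm38, against 0.350% of starts after moving by 1 base. Coordinates are therefore given on GRCm38.

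Total counts ran from 119948 to 240889 per library. All values come from these counts. They were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. CircRNAs were kept by filterByExpr with a minimum count of 5 and a minimum total of 15, which left 7917 circRNAs, of 3188 host genes and 181 without a host gene. Counts were scaled by TMM. The edgeR quasi-likelihood F test was used in 1 fit of the 4 groups over 16 libraries, with a common dispersion of 0.0631, and a circRNA was called at a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. Levels are CPM as edgeR gives them, scaled counts over the scaled total of tested circRNAs, as mean ± SD, and fold changes are log2 with the standard error (SE) of the fit.

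The counts of all circRNAs of a host gene were also summed, which left 3699 host genes, tested in the same way. Before the data were examined, 14 lists of host genes were fixed, along with the tests, the comparisons and the alternatives, except those said to be chosen later: AMPK complex and signalling, sarcomere and Z-disc, calcium handling and ion channels, fatty acid oxidation and mitochondria, extracellular matrix and fibroblast activation, leukocyte markers, endothelial markers, smooth muscle and pericyte markers, erythroid markers, Schwann cell and neuronal markers, adipose and epicardial markers, cell cycle, autophagy and cell death, and regulators of splicing and circRNA formation. Lists with at least 5 measured members, 12 of the 14, were compared with the other host genes by camera on voom values with a preset correlation of 0.01, adjusted over the 12 lists. The erythroid list and the adipose and epicardial list had 4 measured genes each and were not tested. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list changed at all, not whether they changed more than other host genes.

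Named genes followed a rule written before the data were examined. For MIRI against Sham, MIRI+AICAR against MIRI, MIRI+Compound C against MIRI and MIRI+AICAR against MIRI+Compound C, the 10 higher and 10 lower called circRNAs with the smallest p were taken. Where fewer than 5 were called in a direction, the 5 with the smallest p were taken. The 10 circRNAs with the highest mean count, and up to 4 host genes of each list with the smallest p, were added. Identity rests on the identifier and coordinates of the table, and exon numbers are those of a GENCODE transcript with both ends. For the Meis2 and Parp11 circRNAs given with exon numbers, those exons sum to 338 and 651 nucleotides. Their listed spliced lengths were 527 and 736, so the exons inside them may differ.

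Depth, circRNAs detected after thinning every library to 119948 counts (seed 11), and the share of the 10 most abundant circRNAs were compared by exact permutation tests of the difference of means, adjusted over 4 comparisons. Relations between comparisons that share libraries were set beside 20 simulated sets of unchanged groups. Lists chosen later were set beside 10000 random lists matched in 20 bins of expression, with 2000 bootstrap draws and a prior count of 2 for log2 ratios. Alternatives were DESeq2, RLE and total-count scaling, no filter, a minimum count of 10, only the 2 groups compared, voom with quality weights, thinned libraries, host gene sums, unadjusted p under 0.05 with an absolute log2 fold change of at least 1, the replicate number as a block, and leaving out each library of the compared groups. A run without both MIRI replicate 1 and MIRI+AICAR replicate 5 was added after the data were seen.

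The fits were tested on simulated data with 7917 circRNAs, of which 200 were changed, in 3 draws. For MIRI against Sham, 5.33% of 2-fold and 42.7% of 4-fold changes were recovered. For MIRI+AICAR against MIRI the shares were 13.7% and 50.3%, and for MIRI+AICAR against MIRI+Compound C they were 23.0% and 59.0%. Camera called a list shifted by -0.4 in 20 of 20 simulated sets and called 0 other lists. Genes were simulated independently, so these sets cannot show false calls that come from correlated genes. In the real libraries, other splits of MIRI+AICAR and MIRI+Compound C called up to 5 lists. Pairs of replicates differed by more than counting error, with chi-square per degree of freedom from 1.83 to 6.97, so no library was a copy of another. No reads, linear RNA or genome sequence were available, so neither the circRNA calls nor the ratio of circular to linear RNA was checked, and all columns of counts were used.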

Results

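The table gave the number of reads across the back-splice junction of each circRNA, the junction that joins the end of an exon to an earlier exon, in 16 heart libraries. MIRI stands for myocardial ischaemia and reperfusion injury. AICAR activates AMPK, the kinase that senses low cellular energy, and Compound C inhibits it. Total counts were 119948, 151854 and 163551 in Sham, and 157341, 173011 and 124023 in MIRI. MIRI+Compound C libraries held 140677, 182895, 187227, 185487 and 150269 counts, and MIRI+AICAR libraries 178086, 178544, 231839, 240889 and 190944. A count was present for 40381 circRNAs of 6886 host genes, and exonic circRNAs made up 35293 of them. The 7917 tested circRNAs held 87.9% to 91.2% of the counts of each library.

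The most abundant circRNA came from Nfix, a transcription factor gene (novel_circ_060633, mean count 2397 per library, 1.39% of all counts). It was followed by circRNAs of Gigyf2 (novel_circ_003594, 1919), of the sodium-calcium exchanger gene Slc8a1 (novel_circ_027970, 1551), and of Elf2 (novel_circ_041234, 1329). Next came circRNAs of Asph (novel_circ_044015, 1299), of the giant sarcomere protein gene Ttn (novel_circ_036234, 1077), and of Phf21a (novel_circ_039678, 864). The last of the 10 were from Ogdh (novel_circ_010928, 804), Rnf169 (novel_circ_056877, 639) and Rbm4 (novel_circ_031920, 629.6). In edgeR, 0 of these 10 were called in any of the 4 comparisons. The heart genes Ttn and Ryr2, which encodes the calcium release channel, had 155 and 141 circRNAs with a count.

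After thinning to equal depth, MIRI+AICAR libraries held more kinds of circRNA, 14258 ± 678 (SD, n = 5), than MIRI with 12264 ± 1130 (n = 3; exact permutation p = 0.0179, adjusted p = 0.0357) and MIRI+Compound C with 12699 ± 968 (n = 5; exact permutation p = 0.00794, adjusted p = 0.0317). Both are the smallest p these designs allow. The table holds no count of 1, so thinning made such counts in deeper libraries but not in the smallest. With at least 2 counts the difference from MIRI went from 1994 to 235.4 (exact permutation p = 0.0714) and that from MIRI+Compound C from 1559 to 380.8 (exact permutation p = 0.00794). Without MIRI replicate 3 the first gave an exact permutation p = 0.0952. Sham held 11762 ± 908 (n = 3), against which MIRI gave an exact permutation p = 0.50, where 3 against 3 cannot go below 0.10, and MIRI+Compound C against MIRI gave an exact permutation p = 0.554. Mean totals were 145120 ± 22569 in Sham, 151460 ± 25018 in MIRI, 169310 ± 22078 in MIRI+Compound C and 204060 ± 30107 in MIRI+AICAR, with adjusted p from 0.143 to 0.700 by exact permutation. The 10 circRNAs with the highest mean share over all libraries, the same 10 in each, took 7.01% ± 0.472, 7.21% ± 0.685, 7.23% ± 0.458 and 7.37% ± 0.341 of counts in the same order, with adjusted p from 0.933 to 0.964 by exact permutation.

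MIRI against Sham asked what ischaemia and reperfusion did after 1 week. A circRNA of Ddx60, an interferon-induced helicase gene of antiviral defence, was 333 ± 102 CPM in MIRI against 1642 ± 400 in Sham (n = 3 each), so it fell by 2.31 on the log2 scale (SE 0.27, adjusted p = 1.98e-05), and was lower in 3 of 3 MIRI libraries. It is novel_circ_061744, on chromosome 8 from 61979257 to 61983943, and joins coding exons 19 to 21 of 38. A circRNA of Cd84, a receptor gene of leukocytes and platelets, rose from 23.1 ± 23.7 to 196 ± 94.1 CPM (novel_circ_004583, chromosome 1, 171872697 to 171873439, coding exons 4 to 5 of 9; log2 2.94, SE 0.54, adjusted p = 0.0266). Summed over host genes, the interferon-induced transcription factor gene Stat2 (log2 -1.28, SE 0.26, adjusted p = 0.0358) and the xanthine dehydrogenase gene Xdh (log2 -0.77, SE 0.14, adjusted p = 0.0152), named after their values were seen, also fell. They were 2 of 6 host genes called, with Ddx60, Cd84, Itgb3 and Adam10, and the latter pair did not pass in 7 of 14 alternatives each, among them without MIRI replicate 1 (adjusted p = 0.640 and 0.429, from 1.15e-23 and 2.45e-16 up to 0.682 and 0.679 over the alternatives). Stat2 did not pass in 4 of 14 alternatives, among them without Sham replicate 2 (adjusted p = 0.172) or 3 (0.137), in a range of 9.81e-05 to 0.462. Xdh did not pass in 3, among them without Sham replicate 1 (0.0932) or 2 (0.115), in a range of 0.00100 to 0.679.

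In edgeR 2 circRNAs were called, 1 higher and 1 lower, while 540 had an unadjusted p under 0.05, where 396 would be reached by chance, and DESeq2 called 7. Circles next in order did not pass. Higher in MIRI were those of Itgb3 (novel_circ_012691, log2 5.02, adjusted p = 0.149), of Trpc6 (novel_circ_065078, log2 3.66, adjusted p = 0.170), of a region between genes (novel_circ_007238, log2 3.70, adjusted p = 0.205) and of Snx13 (novel_circ_014771, Sham listed at 0, adjusted p = 0.205). The circle between genes stood at 581 CPM in MIRI replicate 3 against 36.5 and 38.3 in MIRI replicates 1 and 2. Lower were those of Stat2 (novel_circ_008228, log2 -1.54, adjusted p = 0.115), Cpeb3 (novel_circ_032910, log2 -0.80, adjusted p = 0.115), Diaph2 (novel_circ_068491, MIRI listed at 0, adjusted p = 0.149) and Xdh (novel_circ_027783, log2 -0.70, adjusted p = 0.205). The Ddx60 call stood in all 16 alternatives. The Cd84 call ended in 6 of 16 alternatives: without Sham replicate 1 (adjusted p = 0.122), Sham replicate 2 (0.239), MIRI replicate 1 (0.139) or both MIRI replicate 1 and MIRI+AICAR replicate 5 (0.110), in a fit of only the 2 groups (0.752), and by voom with quality weights (0.796, the top of a range from 8.64e-05). The number of calls went from 2 to 20 without MIRI replicate 2, to 10 without MIRI replicate 3, to 4 without MIRI replicate 1, and to 1 without Sham replicate 1 or 2, while 3 were called without Sham replicate 3.

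Among host gene lists, camera called leukocyte markers as higher: 16 of 17 measured genes had positive fold changes, with a median log2 of 0.51 (camera adjusted p = 0.00932, and adjusted p = 0.160 with an estimated correlation). None passed alone, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05 in edgeR. Examples are Plcg2, a phospholipase gene of immune receptor signalling (log2 1.19, SE 0.40, adjusted p = 0.254), Dock8 (log2 1.22), Elmo1 (log2 0.81) and the coagulation factor gene F13a1 (log2 0.77). MIRI replicate 1 and MIRI+AICAR replicate 5 also carried high levels of circRNAs of Trpc6, Pde5a, Itgb3 and Med12l, described with Compound C. Without both libraries the leukocyte adjusted p was 0.145. It was 0.0777 without MIRI replicate 1 and 0.0580 without Sham replicate 1, in a range of 0.00167 to 0.145. Of 21 matrix and fibroblast genes, 14 were positive and 6 negative (adjusted p = 0.227). Adjusted over the list alone, the collagen gene Col3a1 (log2 3.71), the TGF-beta binding gene Ltbp1 (log2 0.60) and Runx1 (log2 1.45) were higher, against 0 over all genes. Ltbp1 varied widely between MIRI libraries, at 1114 ± 525 CPM. Cell cycle genes were positive in 10 of 10 (adjusted p = 0.0692), and the other 9 tested lists had adjusted p from 0.106 to 0.887. Cell cycle genes (higher) and sarcomere genes (lower) passed without Sham replicate 2 (adjusted p = 0.00786 and 0.00527), with highest values of 0.195 and 0.502 in other alternatives, cell cycle genes also without MIRI replicate 2 (0.0211), and 5 lists, these included, without MIRI replicate 3 (0.0439 for both). For calcium handling genes the mean was positive with a negative median and camera direction. Among smooth muscle and pericyte genes, Itga1 was lower adjusted over the list alone (log2 -0.74).

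**Figure D1:**
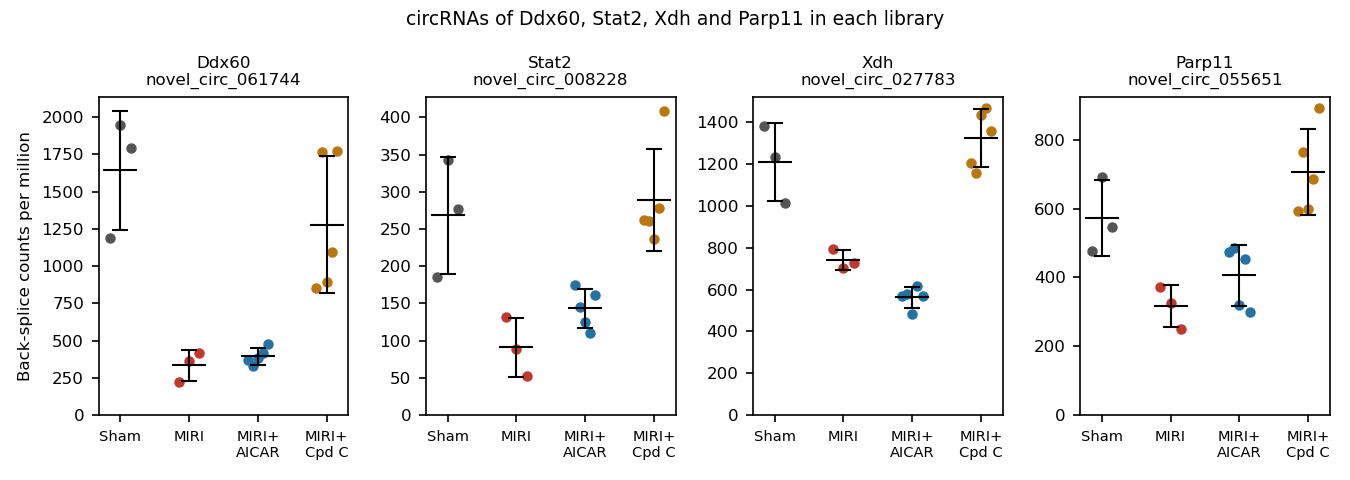
Levels of circRNAs of Ddx60, Stat2, Xdh and Parp11 in each of 16 libraries, in CPM, with points for libraries and bars for the group mean ± SD. The Ddx60 circRNA averaged 1642 CPM in Sham, 333 in MIRI, 396 in MIRI+AICAR and 1277 in MIRI+Compound C.

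MIRI+AICAR against MIRI asked what activating AMPK did in injured hearts. A circRNA of Arhgef40 rose from 67.9 ± 27.8 CPM (n = 3) to 229 ± 69.1 (n = 5; novel_circ_021131, chromosome 14, 51994880 to 51996407, exons 11 to 13 of 24; log2 1.73, SE 0.32, adjusted p = 0.0264). A circRNA of Ttn that joins exons 84 to 118 of 312 fell from 906 ± 413 to 249.5 ± 51.4 CPM (novel_circ_036213, chromosome 2, 76857904 to 76884197; log2 -1.87, SE 0.32, adjusted p = 0.0211), and each MIRI+AICAR library was below each MIRI library. These exons code for the elastic I-band part of the protein. The abundant Ttn circRNA novel_circ_036234 had a log2 fold change of 0.03 (adjusted p = 0.999).

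In edgeR these 2 were called, with 388 at an unadjusted p under 0.05 and 5 calls by DESeq2. Not passing were the higher circRNAs of Diaph2 (novel_circ_068491, MIRI listed at 0, adjusted p = 0.0824), Adamtsl2 (novel_circ_038343, MIRI listed at 0, adjusted p = 0.335), Eif4e3 (novel_circ_053438, log2 1.53, adjusted p = 0.398) and Glis3 (novel_circ_032733, log2 0.89, adjusted p = 0.737). Lower without passing were those of Pdzd2 (novel_circ_022108, log2 -0.52, adjusted p = 0.732), Zeb2 (novel_circ_035433, log2 -1.51, adjusted p = 0.732), Mtmr12 (novel_circ_023462, log2 -0.78, adjusted p = 0.801) and Usp40 (novel_circ_001095, log2 -1.29, adjusted p = 0.801). Without MIRI replicate 1, the library with the highest levels of Trpc6, Pde5a, Itgb3 and Med12l circRNAs, 0 were called and both adjusted p were 0.213. Calls also fell to 0 without MIRI+AICAR replicate 1, 4 or 5, and to 1 without MIRI replicate 3 or MIRI+AICAR replicate 2 or 3. The adjusted p ranged from 0.00318 to 0.295 for Arhgef40 and from 9.91e-21 to 0.224 for Ttn, and the calls ended in 11 and 8 of 18 alternatives.

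No host gene list passed for MIRI+AICAR against MIRI. Of 25 genes of fatty acid oxidation and mitochondria, 18 had negative fold changes (median log2 -0.14, camera adjusted p = 0.0543, and adjusted p = 0.449 with an estimated correlation). That list passed without MIRI replicate 1 (0.00312), without MIRI+AICAR replicate 4 (0.00804) and without both MIRI replicate 1 and MIRI+AICAR replicate 5 (0.0250), and also with a minimum count of 10 (0.0116), single circRNAs (0.0154) or the replicate block (0.0331), in a range of 0.00312 to 0.307. Without MIRI replicate 1, sarcomere genes (lower) and leukocyte markers (higher) passed too (adjusted p = 0.0336 each, up to 0.845 in other alternatives). In the full data leukocyte markers had an adjusted p = 0.253, and Adgre1, the gene of the macrophage marker F4/80, was higher adjusted over the list alone (log2 0.55) but not over all genes. The AMPK complex and signalling list, with 37 of 60 genes measured, had 20 positive and 17 negative members (adjusted p = 0.725) and 0 called genes, with 1 at an unadjusted p under 0.05 in edgeR. Its camera direction was down, against a median log2 of 0.04. The other 9 lists had adjusted p from 0.353 to 0.835 and 0 called genes. Median, mean and camera direction also differed in sign for calcium handling, endothelial, Schwann cell and splicing genes.

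MIRI+Compound C against MIRI asked what inhibiting AMPK did in injured hearts. Circles of 4 genes rose. That of Ddx60 rose from 333 ± 102 CPM (n = 3) to 1277 ± 460 (n = 5; log2 1.94, SE 0.25, adjusted p = 0.000164) and that of Stat2 from 90.9 ± 39.7 to 289 ± 68.6 (novel_circ_008228, chromosome 10, 128277644 to 128278817, exons 5 to 8 of 24; log2 1.64, SE 0.30, adjusted p = 0.0150). That of the ADP-ribosyltransferase gene Parp11 rose from 316 ± 60.9 to 707 ± 125 CPM (novel_circ_055651, chromosome 6, 127468032 to 127478129, exons 2 to 7 of 9; log2 1.15, SE 0.21, adjusted p = 0.0150). That of Xdh, whose enzyme makes uric acid and can release oxidants, rose from 742 ± 48.0 to 1325 ± 138 CPM (novel_circ_027783, chromosome 17, 73906010 to 73907745, exons 21 to 24 of 36; log2 0.84, SE 0.15, adjusted p = 0.0150). A second Xdh circRNA did not pass (novel_circ_027787, log2 1.12, adjusted p = 0.0765).

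The 3 circRNAs that fell came from Trpc6, a cation channel gene (novel_circ_065078, chromosome 9, 8634047 to 8658377, exons 4 to 10 of 13; 169.7 ± 23.6 against 1737 ± 2584 CPM, adjusted p = 0.0396), and from Pde5a, the gene of the cyclic GMP phosphodiesterase (novel_circ_043532, chromosome 3, exon 2 of 21, 122 ± 27.8 against 826 ± 1161 CPM, adjusted p = 0.0450; and novel_circ_043549, exons 8 to 11, 80.6 ± 20.1 against 476 ± 594 CPM, adjusted p = 0.0499). Their fall rested on MIRI replicate 1. Summed over circRNAs, Trpc6 stood at 4753 CPM in that library against 212 and 247 in MIRI replicates 2 and 3, and Pde5a at 5567 against 459 and 419.9. Without it the log2 fold changes of the 3 circRNAs were -0.52, -0.36 and -0.76, with adjusted p = 0.999, 0.999 and 0.974. The calls ended in 11 of 17, 11 of 17 and 12 of 18 alternatives, with adjusted p from 5.02e-57, 1.87e-23 and 3.73e-13 up to 1.00, 1.00 and 0.974. Itgb3, the gene of the platelet fibrinogen receptor chain, stood at 1233 CPM against 35.3 and 57.6, and Med12l at 3093 against 282 and 428. MIRI+AICAR replicate 5 had the next highest levels, 1187 CPM for Trpc6, 1635 for Pde5a, 250.2 for Itgb3 and 1134 for Med12l. All these sums are scaled over host genes with a total of at least 15 counts. They are therefore not on the scale of the CPM of single circRNAs. The single circRNAs of Itgb3 (novel_circ_012691, log2 -3.33) and Med12l (novel_circ_042775, log2 -2.25) did not pass (adjusted p = 0.0866 each).

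In edgeR 7 circRNAs were called, 4 higher and 3 lower, with 512 at an unadjusted p under 0.05. DESeq2, without an adjusted p for 5532 circRNAs, called 13, with 4 of the 7 among them. Without both libraries 8 were called, and the 4 higher circRNAs were among them. Leaving out 1 library gave 29 calls without MIRI replicate 2, 18 without MIRI replicate 3, and 3 to 5 without any single MIRI+Compound C library. The Ddx60 call stood in all 18 alternatives. A fit of only the 2 groups called 1 circRNA, that of Ddx60, and 2 of the 7 were among the 4 called with the replicate block. Stat2 did not pass in the fit of only the 2 groups (adjusted p = 0.0819, the top of its range from 0.000679), with the replicate block (0.0511), or without MIRI replicate 3 (0.0590) or MIRI+Compound C replicate 5 (0.0579). Parp11 did not pass in the fit of only the 2 groups (0.0531), without these libraries (0.0590 and 0.0579) or without MIRI+Compound C replicate 2 (0.0547), within 7.37e-05 to 0.0590. Xdh did not pass in the fit of only the 2 groups (0.0531, the top of its range from 3.47e-05) or with the replicate block (0.0511).

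**Figure D2:**
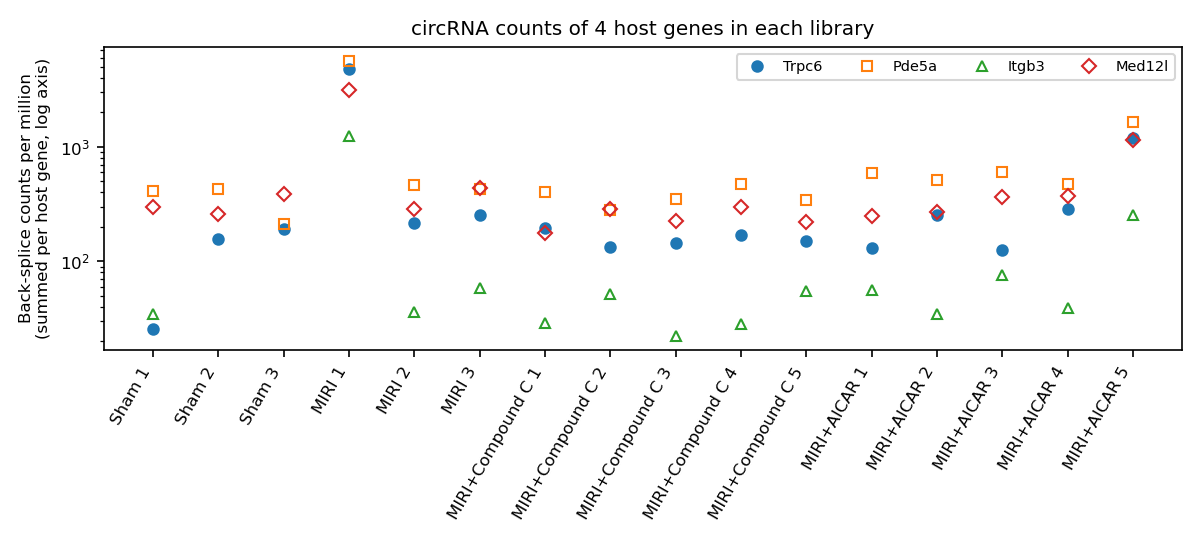
Summed circRNA levels of Trpc6, Pde5a, Itgb3 and Med12l in each of 16 libraries, in CPM on a logarithmic axis, with 1 point per library. Scaled over host genes with a total of at least 15 counts, as in the text, Trpc6 stood at 4753 CPM in MIRI replicate 1 and 1187 in MIRI+AICAR replicate 5. Points are scaled over the tested host genes, so their values differ from these. Itgb3 was listed at 0 in Sham replicates 2 and 3, which are not drawn.

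By list, camera called endothelial markers as higher with Compound C: 11 of 16 were positive and 5 negative, with a median log2 of 0.42 (camera adjusted p = 0.0167, and adjusted p = 0.278 with an estimated correlation). None was called over all genes. Adjusted over the list alone, the VEGF receptor gene Flt1 (log2 0.65, SE 0.18) and Adgrf5 (log2 0.80) were higher and the von Willebrand factor gene Vwf, also a platelet product, was lower (log2 -1.97). The list did not pass without MIRI replicate 2 (adjusted p = 0.0684), without MIRI+Compound C replicate 1 (0.0631) or on single circRNAs (0.161), in a range of 0.00476 to 0.161. Of 21 matrix and fibroblast genes, Ltbp1 fell from 1114 ± 525 to 599 ± 28.3 CPM (log2 -0.90, SE 0.18, adjusted p = 0.0139), but did not pass in 6 of 16 alternatives, and its log2 fold change was -0.43 without MIRI replicate 1 (adjusted p = 0.478, the highest of a range from 9.26e-06). Adjusted over the list alone, Itga8 was lower (log2 -2.23) and Sparc higher (log2 2.63), and the list did not pass (adjusted p = 0.878). In their lists alone, the fatty acid transporter gene Cd36 (log2 0.48) and Itga1 (log2 0.67) were higher. Sarcomere genes and smooth muscle and pericyte genes had adjusted p of 0.145 each, the latter passing without MIRI replicate 3 (0.0412) or on single circRNAs (0.0108) and reaching 0.845 without MIRI replicate 1. Calcium handling genes passed without MIRI+Compound C replicate 1 (adjusted p = 0.0383, and up to 0.899). The adjusted p was 0.361 for the AMPK list, with 0 called and 1 at an unadjusted p under 0.05 in edgeR, and 0.251 to 0.878 for the other 7 lists. Median, mean and camera direction differed in sign for matrix and splicing genes.

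MIRI+AICAR against MIRI+Compound C set the activator against the inhibitor in 5 libraries each. Here and below, for this pair, fell, rose, lower and higher describe AICAR relative to Compound C, not to MIRI. They do not say which drug moved a circRNA. Against MIRI, Ddx60 had log2 fold changes of 0.26 with AICAR and 1.94 with Compound C. Those of Meis2 novel_circ_036754 were 0.23 and -0.90, and those of Ttn novel_circ_036213 -1.87 and 0.18. In edgeR 44 circRNAs were called, 20 higher and 24 lower with AICAR, while 674 had an unadjusted p under 0.05. DESeq2, which gave no adjusted p for 5532 of the 7917 circRNAs, called 77, with 32 of the 44 among them. Xdh novel_circ_027783 was lower with AICAR than with Compound C, at 563 ± 49.9 against 1325 ± 138 CPM (log2 -1.24, SE 0.13, adjusted p = 1.16e-06). So were Xdh novel_circ_027787 (log2 -1.31, SE 0.20, adjusted p = 0.000778) and Ddx60, at 396 ± 57.4 against 1277 ± 460 CPM (log2 -1.69, SE 0.20, adjusted p = 1.44e-05). Stat2 (log2 -1.01, adjusted p = 0.0311) and Parp11 (log2 -0.80, adjusted p = 0.0218), named here after their values were seen, were also lower than with Compound C. Ttn novel_circ_036213 fell from 1039 ± 704 to 249.5 ± 51.4 CPM (log2 -2.05, SE 0.29, adjusted p = 0.000218), the growth factor gene Pdgfd from 963 ± 199 to 484 ± 98.3 (novel_circ_065050, chromosome 9, exons 2 to 3 of 7; log2 -0.99, SE 0.16, adjusted p = 0.00102), and Fhl2, a gene for a sarcomere-associated LIM protein, from 4187 ± 417 to 2549 ± 225 (novel_circ_000420, chromosome 1, 43141698 to 43153254, exons 2 to 3 of 6; log2 -0.71, SE 0.12, adjusted p = 0.00220). Cpeb3, a gene for an RNA-binding regulator of translation, fell from 3239 ± 334 to 1945 ± 279 CPM (novel_circ_032910, log2 -0.74, SE 0.13, adjusted p = 0.00538).

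Higher with AICAR was a circRNA of Meis2, a homeobox transcription factor gene, at 250.4 ± 36.9 against 113 ± 26.9 CPM (novel_circ_036754, chromosome 2, 115921672 to 116049198, exons 7 to 9 of 12; log2 1.13, SE 0.21, adjusted p = 0.00808), higher in 5 of 5 libraries than in any with Compound C. The phospholipase gene Plce1 (novel_circ_034173, 494 ± 73.1 against 261 ± 65.4 CPM; log2 0.91, SE 0.19, adjusted p = 0.0166) and the fibroblast growth factor receptor gene Fgfr2 (novel_circ_057522, 76.0 ± 37.6 against 13.1 ± 12.1 CPM; log2 2.46, SE 0.53, adjusted p = 0.0218) rose too. Overlapping circRNAs of Rp1, a gene best known from photoreceptors, rose, led by novel_circ_000026 (chromosome 1, 4197534 to 4231144, exons 13 to 17 of 30; 155 ± 125 against 15.9 ± 17.5 CPM, log2 3.15, SE 0.59, adjusted p = 0.00808), with novel_circ_000028 (log2 2.96, adjusted p = 0.00808) and novel_circ_000025 (log2 3.15, adjusted p = 0.0218). The rest of the 10 higher were circRNAs between genes (novel_circ_065428, log2 1.24, adjusted p = 0.0127; novel_circ_042024, log2 3.26, adjusted p = 0.0218), Clip4 (novel_circ_029114, log2 1.00, adjusted p = 0.0224) and Tmem26 (novel_circ_007475, log2 2.39, adjusted p = 0.0249). The rest of the 10 lower were Rftn1 (novel_circ_027483, log2 -0.63, adjusted p = 0.00808), Lnx1 (novel_circ_048575, log2 -1.78, adjusted p = 0.00842) and Pdzd2 (novel_circ_022108, log2 -0.60, adjusted p = 0.00970).

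The calls on Meis2, both Xdh circles, Ddx60, Ttn novel_circ_036213, Pdgfd, Fhl2, Cpeb3 and Lnx1 stood in every alternative that gave an adjusted p (DESeq2 gave none for Lnx1). Without MIRI+AICAR replicate 3, 10 circRNAs were called, and those of Rp1 (adjusted p = 0.0531, 0.0709 and 0.214), Fgfr2 (0.125), Rftn1 (0.0531) and Pdzd2 (0.0688) were not. The circRNAs of Stat2 and Parp11 were not both among these 10. The Rp1 circRNAs did not pass in 2 of 20, 2 of 19 and 7 of 18 alternatives (adjusted p up to 0.266), Fgfr2 in 7 of 19 (up to 0.138), and Rftn1 and Pdzd2 in 1 of 20 each. Plce1 did not pass without MIRI+Compound C replicate 5 (0.0781, the top of its range), 3 (0.0517) or MIRI+AICAR replicate 5 (0.0520). The remaining 4 higher circRNAs did not pass in 3 to 9 alternatives each, with adjusted p up to 0.275. Counts over 1.5 times lower came without MIRI+Compound C replicate 1 (23), 3 (24), 4 (27) or 5 (20), and without MIRI+AICAR replicate 1 (28), 2 (23) or 5 (26). Without both MIRI replicate 1 and MIRI+AICAR replicate 5, 46 were called and 34 of the 44 were among them.

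Of the 12 host gene lists, camera called 5 between the drugs, against 0 with an estimated correlation and 7 by fry in one direction. With AICAR, endothelial markers were lower than with Compound C in 14 of 16 genes (median log2 -0.42, camera adjusted p = 0.000129, and adjusted p = 0.0774 with an estimated correlation), and Flt1 fell from 577 ± 75.9 to 312 ± 55.1 CPM (log2 -0.88, SE 0.15, adjusted p = 0.00114). Adjusted over the list alone, 4 were lower (Flt1, Ets1, Adgrf5 and St6galnac3) and Vwf was higher, against 1 lower over all genes. Genes of fatty acid oxidation and mitochondria were lower in 19 of 25 (median log2 -0.33, camera adjusted p = 0.000667, and adjusted p = 0.0774 with an estimated correlation). In MIRI+AICAR replicate 5 this list had a median log2 ratio of -0.23 to the other MIRI+AICAR libraries, and without that library its adjusted p was 0.00231, in a range of 2.51e-07 to 0.00847. Cd36, the fatty acid transporter gene, fell from 2164 ± 131 to 1358 ± 214 CPM (log2 -0.67, SE 0.12, adjusted p = 0.00114) and Oxct1, a gene of ketone body use, by 0.41 (SE 0.10, adjusted p = 0.0274). Adjusted over the list alone, Acadm (log2 -0.80), Etfb and Idh2 (log2 -1.55) were lower as well, 5 in all against 2 over all genes. Sarcomere and Z-disc genes were lower in 16 of 21 (median log2 -0.38, camera adjusted p = 0.00103, and adjusted p = 0.0851 with an estimated correlation). Ttn fell from 10187 ± 999 to 7590 ± 1044 CPM over all its circRNAs (log2 -0.42, SE 0.11, adjusted p = 0.0452), and adjusted over the list alone the cardiac myosin gene Myh6 (log2 -0.51) and Fhod3 (log2 -0.38) were lower too.

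Leukocyte markers were higher with AICAR in 15 of 17 genes (median log2 0.40, camera adjusted p = 0.0127, and adjusted p = 0.0851 with an estimated correlation). In edgeR 0 were called, over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05, among them Adgre1 (log2 0.43, adjusted p = 0.101). MIRI+AICAR replicate 5 had the second highest levels of circRNAs of Trpc6, Pde5a, Itgb3 and Med12l. In it, leukocyte genes had a median log2 ratio of 0.35 to the other MIRI+AICAR libraries. Without that library the leukocyte adjusted p was 0.0450, the highest of a range from 0.00375. Cell cycle genes were higher in 9 of 10 (median log2 0.44, camera adjusted p = 0.0319, and adjusted p = 0.152 with an estimated correlation), with 0 called and 1 at an unadjusted p under 0.05 in edgeR. That list did not pass with a minimum count of 10 (adjusted p = 0.119), on single circRNAs (0.0627), without MIRI+Compound C replicate 1, 2 or 3 (adjusted p = 0.108, 0.0572 and 0.0584), without MIRI+AICAR replicate 1, 2 or 5 (0.0552, 0.0726 and 0.135) or without both MIRI replicate 1 and MIRI+AICAR replicate 5 (0.0834), within 0.00842 to 0.135.

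Of 21 matrix and fibroblast genes, 15 were positive and the list did not pass by camera (adjusted p = 0.166), but did by fry (adjusted p = 0.0275 in one direction and 0.00477 in either). The integrin gene Itga8 rose from 22.3 ± 13.3 to 161 ± 128 CPM (log2 2.83, SE 0.62, adjusted p = 0.00896) but did not pass without MIRI+AICAR replicate 3 (adjusted p = 0.0979, the highest of a range from 7.07e-11). Ltbp1 (log2 0.46) was higher and Sparc (log2 -1.86) lower adjusted over the list alone. The potassium channel subunit gene Abcc9, a pericyte marker, fell by 0.47 (adjusted p = 0.0496, and up to 0.170 in the alternatives), and Itga1 (log2 -0.44) was lower adjusted over the smooth muscle and pericyte list alone, which did not pass (adjusted p = 0.325, but 0.00212 on single circRNAs and up to 0.567). The AMPK complex and signalling list had 15 positive and 22 negative members and a median log2 of -0.06. It did not pass by camera (adjusted p = 0.170, and adjusted p = 0.152 with an estimated correlation) but did by fry (adjusted p = 0.0257 in one direction, lower with AICAR, and 0.0209 in either). It had 0 calls in edgeR with 4 at an unadjusted p under 0.05, among them Lipe (log2 -1.07), Cpt1a (log2 -0.86) and Pfkfb3 (log2 -1.45). Adjusted p was 0.252 for calcium handling and ion channels (0.0121 without MIRI+Compound C replicate 1, and up to 0.723), 0.684 for autophagy and cell death (median positive, mean negative), and 0.606 for Schwann cell and neuronal markers, of which Cdh19 (Compound C listed at 0) was higher adjusted over the list alone. It was 0.903 for regulators of splicing and circRNA formation (0.0160 by fry in either direction), where camera gave a downward direction against a median log2 of 0.10. The Oxct1, Ttn and Abcc9 calls ended in 7, 9 and 11 of 18 alternatives, most of which left out 1 library, with adjusted p up to 0.111, 0.145 and 0.170.

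**Figure D3:**
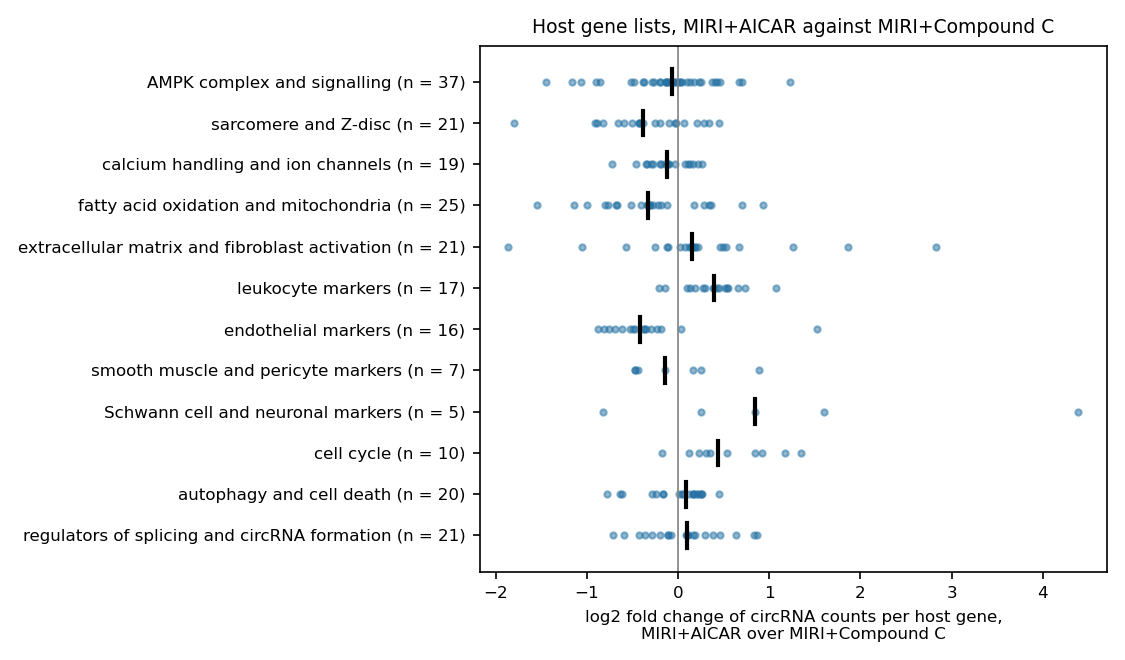
Log2 fold changes of MIRI+AICAR against MIRI+Compound C for host genes of the 12 tested lists, with a point per gene and a bar at the median of the list. The medians were -0.42 for endothelial, -0.38 for sarcomere, -0.33 for oxidation, 0.40 for leukocyte and 0.44 for cell cycle genes.

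The treated groups were also set against Sham. MIRI+AICAR differed by 37 circRNAs in edgeR, 19 higher and 18 lower, with 824 at an unadjusted p under 0.05. DESeq2, without an adjusted p for 6605 circRNAs, called 78, with 23 of the 37 among them. A circRNA of Glis3, a transcription factor gene, rose from 81.2 ± 29.7 to 312 ± 53.5 CPM (novel_circ_032733, log2 1.92, adjusted p = 0.000214). Against Sham it was also higher, without passing, in MIRI+Compound C (log2 1.23, adjusted p = 0.214) and in MIRI (log2 1.02, adjusted p = 0.376). In MIRI+AICAR the circRNAs of other genes fell. Ddx60 (log2 -2.05, adjusted p = 3.42e-06), Xdh novel_circ_027783 (log2 -1.10, adjusted p = 9.32e-05), Cpeb3 (log2 -1.01, adjusted p = 0.000367), Pdzd2 (log2 -0.85, adjusted p = 0.000677), Ttn novel_circ_036213 (log2 -1.99, adjusted p = 0.00115) and Fhl2 (log2 -0.80, adjusted p = 0.00244) fell. MIRI+Compound C against Sham gave 0 calls in edgeR, with 409 at an unadjusted p under 0.05 and 1 call by DESeq2, and Ddx60 had a log2 fold change of -0.37 (adjusted p = 0.997). Calls for MIRI+AICAR fell to 16 without MIRI+AICAR replicate 3, to 24 without replicate 5, to 20 without Sham replicate 1 and to 19 without Sham replicate 2, and those for MIRI+Compound C went to 4 without Sham replicate 3.

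Relations between comparisons were computed across 7917 circRNAs, which are not independent replicates. The log2 fold changes against MIRI of the 2 drugs had a Pearson correlation of 0.662, and simulated unchanged groups set against the same MIRI libraries gave 0.733. The covariance was 0.429 against a simulated 0.565. Injury and AICAR fold changes gave -0.505 against a simulated -0.596 (covariance -0.392 against -0.554), and injury and Compound C gave -0.596 against -0.583 (covariance -0.524 against -0.553). The AICAR and Compound C correlation lay outside the range of the simulated values, 0.702 to 0.745, and so did that of injury with AICAR, outside -0.618 to -0.562, both nearer 0. That of injury with Compound C lay within -0.621 to -0.549. These ranges may be too narrow, since real circRNAs can vary together within a library. They do not decide whether the responses differ. The 3 libraries of the shared MIRI group were not divided between the comparisons. AICAR and Compound C shared 0 calls against MIRI, where independence gives 0.001. Ddx60 was called in MIRI against Sham and, in the opposite direction, in MIRI+Compound C against MIRI.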

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

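Tests of a scaling factor, of depth, of dilution, of the share of cardiomyocytes and of scar, and the run without both MIRI replicate 1 and MIRI+AICAR replicate 5, were chosen after the result was seen; the others below were written before it. The platelet and interferon lists were written after the patterns had been noticed and before the lists were measured.

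In 10 of 102 groups of 5 libraries, 1 library lay far from the other 4, where chance gives about 1 in 20 groups, or 5. MIRI+AICAR replicate 5 stood out in 4 of them: the Trpc6 circRNA novel_circ_065078 at 1301 CPM (others 140.3 to 304), the Pde5a circRNA novel_circ_043532 at 617.4 (125 to 189), the Med12l circRNA novel_circ_042775 at 875.1 (157 to 289) and the Eif4e3 circRNA novel_circ_053438 at 203.8 (99.7 to 115). MIRI+AICAR replicate 1 had the Arhgef40 circRNA novel_circ_021131 at 348.8 CPM (170.4 to 209.8), and MIRI+AICAR replicate 2 the Snx13 circRNA novel_circ_014771 at 88.11 (40.1 to 48.2). MIRI+Compound C replicate 5 had the Itgb3 circRNA novel_circ_012691 at 58.43 CPM (24.2 to 31.1) and the Stat2 circRNA novel_circ_008228 at 409 (236 to 278). MIRI+Compound C replicate 1 had the Ttn circRNA novel_circ_036213 at 2262 CPM (581 to 1001) and the Rbm4 circRNA novel_circ_031920 at 3258 (4076 to 4338), the only one of these below its group.

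CircRNAs of Trpc6, Pde5a, Itgb3 and Med12l were 10.9 to 35.3 times as high in MIRI replicate 1 as in the median of the libraries other than MIRI+AICAR replicate 5. A wrong scaling factor is excluded, because the lowest log2 ratio of the 4 genes lay 3.08 above the median of all tested host genes, which a factor would move alike. Platelet or megakaryocyte RNA is a candidate source: a separate list of 71 such genes, 23 of them measured, had a median log2 ratio of 1.15 to the other MIRI libraries (bootstrap range 0.59 to 2.72, above every random list, 19 of 23 positive), with its most abundant members Stxbp5 at 1.86, Rap1b at 1.51, Kif2a at 1.15 and Parvb at 3.29. Of the 23, 20 also had counts in Sham hearts and 0 are in a fixed list, no sort is described that would remove platelets, and the list gave 0.28 in MIRI+AICAR replicate 5 (-0.08 to 0.58, percentile 97.34, 14 of 23 positive), where platelet RNA was not shown. Whole blood stays open: the 4 measured erythroid genes had a median of -0.23 and leukocyte genes 0.29, but Xpo7, Epb41 and Tfrc (log2 ratios -0.14 to -0.29) averaged a log2 CPM of 7.67 to 8.17 over the libraries, a baseline that would hide a small share, while Ank1 (log2 ratio -1.08), 1 gene at a low level of 4.07, went against it, and no biological explanation from the design was tested, as the pattern lies within groups.

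CircRNAs of Ddx60, Stat2, Xdh and Parp11 had lower means in MIRI and MIRI+AICAR than in Sham and MIRI+Compound C. They are the circRNAs called higher in MIRI+Compound C against MIRI, so their median log2 of 1.39 there (4 called) is no separate support. The median was -1.20 in MIRI against Sham (1 of 4 called) and -1.12 in MIRI+AICAR against MIRI+Compound C (4 called). In MIRI+AICAR against Sham, which shares no library with MIRI+Compound C against MIRI, it was -1.01 (2 called). There Stat2 (adjusted p = 0.127) and Parp11 (0.327) did not pass. Depth and dilution by platelet RNA are argued against as the whole cause, since the Compound C against MIRI median was 1.46 after thinning to equal totals and 1.51 without MIRI replicate 1 and MIRI+AICAR replicate 5, with 4 of 4 called each time. A separate list of 106 interferon-inducible genes, 20 of them tested and 0 called in edgeR (1 to 6 at an unadjusted p under 0.05), had a median of -0.45 in MIRI+AICAR against MIRI+Compound C (bootstrap range -0.60 to -0.30, percentile 0.03 of random lists, 16 negative), -0.46 in MIRI against Sham (-0.94 to 0.01, percentile 0.29, 14 negative) and 0.65 in MIRI+Compound C against MIRI (0.47 to 1.21, percentile 100, 18 positive). In MIRI+AICAR it was 0.23 against MIRI (-0.04 to 0.87, percentile 88.77, 13 positive) and -0.14 against Sham (-0.38 to 0.24, percentile 10.09, 12 negative), so the list was not shown to be low with AICAR relative to Sham, and in MIRI+Compound C against Sham it was 0.22 (0.02 to 0.55, percentile 87.57, 15 positive). A lower interferon response after injury that is not seen with Compound C may account for part of the pattern, as a hypothesis found and tested on the same data, but a shared day of collection or library preparation for Sham with MIRI+Compound C cannot be told apart from the groups, because 0 labels give a day or batch.

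Between the drugs, camera gave the endothelial, sarcomere and oxidation lists as lower and the leukocyte list as higher with AICAR, but adjusted p was 0.0774, 0.0851, 0.0774 and 0.0851 with an estimated correlation, and 5 of 100 splits of the libraries called as many lists, so chance was not excluded. The 4 lists still passed after thinning to equal totals, with a highest camera adjusted p of 0.0151. The lowest read counts were missing before thinning, however, and thinning cannot undo a loss that may differ with depth. Greater depth of the MIRI+AICAR libraries therefore stays open. A lower share of cardiomyocytes alone would raise the markers of every other cell type, whereas the endothelial median was -0.42. More infarct scar in the sampled pieces stays open, because matrix and fibroblast genes had a camera adjusted p = 0.166 against 0.0275 by fry in one direction, with members on both sides of 0. The drugs themselves, which the design names, stay open too and cannot be parted from differences in infarct size, which the labels do not give.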

How the results depend on the processing

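The run without both MIRI replicate 1 and MIRI+AICAR replicate 5 was chosen after seeing the data; the other alternatives were fixed before the data were examined. Among values of single circRNAs and host genes under alternatives, 3858 kept their direction and side of the threshold, 563 dropped below it, 79 passed it and 4 changed sign. Among values of the main results, 188 stayed, 102 moved by more than 1.5 times or by more than the simulated spread, 8 lost significance and 16 changed sign. Where no cause is named, the cause was not tested. Low counts limit the calls in simulated data: for MIRI against Sham 42.7% of 4-fold changes were recovered, and 75.2% in the upper part of expression, with 50.3% and 82.5% for MIRI+AICAR against MIRI and 59.0% and 87.6% for MIRI+AICAR against MIRI+Compound C. Depth was not varied there.

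Numbers of called circRNAs are given for MIRI against Sham, MIRI+AICAR against MIRI, MIRI+Compound C against MIRI, MIRI+AICAR against MIRI+Compound C, MIRI+AICAR against Sham and MIRI+Compound C against Sham, in this order, against 2, 2, 7, 44, 37 and 0. DESeq2 called 7, 5, 13, 77, 78 and 1. No filter on low counts gave 50, 29, 71, 103, 92 and 20, sums per host gene 6, 1, 22, 72, 73 and 1, and an unadjusted p under 0.05 with a log2 fold change of at least 1 gave 382, 224, 312, 274, 471 and 251. With a minimum count of 10 MIRI+AICAR against MIRI had 0 and MIRI+Compound C against MIRI 4. With only the 2 groups compared, MIRI against Sham had 1, MIRI+Compound C against MIRI 1 and MIRI+AICAR against MIRI+Compound C 81. Voom with quality weights gave 1, 0 and 4 in the first 3 comparisons and 24 for MIRI+AICAR against Sham. Without both MIRI replicate 1 and MIRI+AICAR replicate 5, MIRI against Sham had 5 and MIRI+AICAR against MIRI 1. RLE and total-count scaling and thinned libraries kept all 6 counts within 1.5 times, but thinning changed which circRNAs were called. With thinned libraries, 32 were called for MIRI+AICAR against MIRI+Compound C, and 26 of the 44 were among them. For MIRI+AICAR against Sham 36 were called, with 29 of the 37 among them. Leaving out 1 library of the compared groups gave 1 to 20, 0 to 2, 3 to 29, 10 to 45, 16 to 39 and 0 to 4, and leaving out 1 library of the other groups, which changes the shared fit, gave 2, 2 to 3, 4 to 12, 38 to 61, 35 to 55 and 0.

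For the lists, an estimated correlation gave 0 for MIRI against Sham, 0 for MIRI+Compound C against MIRI and 0 for MIRI+AICAR against MIRI+Compound C. Fry in one direction gave 0 and 0 for the first pair of these, and fry in either direction 0 for MIRI against Sham. MIRI+AICAR against MIRI went from 0 to 1 with a minimum count of 10, with single circRNAs and without both of the libraries named above, the last of which took MIRI against Sham from 1 to 0. Leaving out 1 library of the compared groups gave 0 to 5 lists for MIRI against Sham, 0 to 3 for MIRI+AICAR against MIRI and 0 to 2 for MIRI+Compound C against MIRI. The MIRI+AICAR against MIRI+Compound C count was 7 by fry in one direction, which added the AMPK and matrix lists, 7 by fry in either direction, which added these and the splicing list without the cell cycle list, 6 on single circRNAs, and 4 or 5 in the runs that left out libraries, with a minimum count of 10, with total counts and with the replicate block.

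The replicate numbers gave little sign of pairing: 20 correlations between libraries of the same number ran from -0.02 to 0.08 and 0 passed 0.1. Those between libraries numbered 1 were all positive, from 0.01 to 0.08. Libraries of different numbers were not compared, so a weak structure shared by the libraries numbered 1 is not excluded. With the replicate block MIRI+AICAR against MIRI had 1 circRNA and 1 list, and MIRI+Compound C against MIRI had 4 circRNAs, 2 of them among the 7.

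With at least 2 counts, the difference in circRNAs detected was 235.4 for MIRI+AICAR against MIRI (exact permutation p = 0.0714), fell to 380.8 for MIRI+AICAR against MIRI+Compound C (exact permutation p = 0.00794) and reversed to -145.4 for MIRI+Compound C against MIRI. Leaving out 1 library gave -22.0 to 1154 for MIRI against Sham, 1343 to 2348 for MIRI+AICAR against MIRI and -217 to 794 for MIRI+Compound C against MIRI. For total counts it gave -6244 to 20058 for MIRI against Sham and 38884 to 63378 for MIRI+AICAR against MIRI. The share of counts in the 100 most abundant circRNAs differed by -0.590 for MIRI against Sham, -0.164 for MIRI+AICAR against MIRI and -0.577 for MIRI+AICAR against MIRI+Compound C, reversing the differences for the 10 most abundant. Leaving out 1 library, these ran from -0.118 to 0.562, -0.201 to 0.479 and -0.0530 to 0.250, and from -0.340 to 0.340 for MIRI+Compound C against MIRI.

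The correlation of the AICAR and Compound C responses was 0.587 with a minimum count of 10, 0.776 without MIRI replicate 1 and MIRI+AICAR replicate 5, and 0.794 to 0.824 without 1 MIRI library. That of injury with AICAR was -0.399, -0.668 and -0.716 to -0.656, and that of injury with Compound C was -0.710 without both and -0.752 to -0.708 without 1 MIRI library. Fewer MIRI libraries raise the part that shared libraries give, as in the runs without MIRI libraries. The cause of the shifts with a minimum count of 10 was not tested. Signs of single host genes turned for Ltbp1 in MIRI+AICAR against MIRI, at 0.0343 without both and -0.63 to 0.0442 without 1 library, and for Dlg2, at -0.30 to 3.46 in MIRI against Sham and -3.07 to 0.37 in MIRI+Compound C against MIRI.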

Other observations

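The host genes in this paragraph and the next were chosen after their values were seen, and stand for no tested group. In MIRI+AICAR hearts against Sham, 73 host genes were called, 43 higher and 30 lower. The transcription factor gene Glis3 rose from 194 ± 37.6 CPM (n = 3) to 620.1 ± 92.0 (n = 5; log2 1.66, SE 0.20, adjusted p = 5.53e-06). It was not particular to AICAR, as Glis3 was also called in MIRI+Compound C against Sham (log2 1.10, SE 0.21, adjusted p = 0.0411). Adgre1, the gene of F4/80, rose from 930 ± 237 to 1697 ± 200 CPM (log2 0.86, SE 0.16, adjusted p = 0.00252), as did the cytokine receptor gene Csf2rb2 (adjusted p = 0.00252) and the integrin gene Itgam (adjusted p = 0.0147). Bnc2 rose from 4.25 ± 7.36 to 113 ± 26.2 CPM (adjusted p = 0.00122) and the collagen gene Col3a1 from 4.25 ± 7.36 to 142 ± 28.2 (adjusted p = 0.0118). The metalloprotease gene Adam12 rose from 4.53 ± 7.85 to 87.3 ± 35.6 CPM (adjusted p = 0.0178). These Sham levels, and those of Itgam (4.25 ± 7.36 CPM) and Csf2rb2 (8.50 ± 14.7), lie near the floor, where a listed 0 can have had 1 read. Pdgfb, a platelet-derived growth factor gene, fell from 373 ± 32.8 to 169 ± 27.9 CPM (log2 -1.15, SE 0.19, adjusted p = 0.000732) and Pdgfd by 0.75 (SE 0.14, adjusted p = 0.00252). Glis3, Bnc2, Adgre1, Csf2rb2, Pdgfb and Pdgfd passed in all 16 alternatives. Without Sham replicate 1 or 2, Col3a1 and Itgam did not (up to 0.0777 and 0.0893 in 16 alternatives), and Itgam also not without MIRI+AICAR replicate 3. Adam12 did not pass without Sham replicate 1 or 3 (up to 0.105), and the called genes Slc8a1 (log2 0.78, adjusted p = 0.0490) and Bmp6 (log2 -0.99, adjusted p = 0.0405) did not in 7 and 9 alternatives (up to 0.254 and 0.365).

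Between the drugs, 72 host genes were called, 34 higher and 38 lower with AICAR than with Compound C. Fell and rose again describe AICAR relative to Compound C, and do not say which drug moved a gene. Efnb2, an arterial endothelial signalling gene, fell by 0.60 (SE 0.13, adjusted p = 0.00852) and Dtx3l, an interferon-inducible ubiquitin ligase gene, by 0.71 (adjusted p = 0.00293), both in all 18 alternatives. Nox4, the gene of an oxidase that makes hydrogen peroxide, rose from 104 ± 37.2 to 323 ± 93.6 CPM (log2 1.59, SE 0.39, adjusted p = 0.0223), and the natriuretic peptide clearance receptor gene Npr3 rose by 1.20 (SE 0.29, adjusted p = 0.0210). Nox4 did not pass without MIRI+Compound C replicate 1 (adjusted p = 0.0885) or 5 (0.0845) or MIRI+AICAR replicate 3 (0.0995, the highest of a range from 1.09e-09). Npr3 did not pass in 6 of 18 alternatives, each without 1 library, with adjusted p up to 0.106 without MIRI+AICAR replicate 3.

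Other splits of the same libraries, planned before the data were examined, gave the following. For MIRI+AICAR against MIRI+Compound C, 1 of 100 splits, the real one, called as many as its 44 circRNAs and the highest other called 2. For MIRI+AICAR against Sham, 1 of 56 splits reached 37 and the highest other called 1. For MIRI+Compound C against MIRI, 1 of 56 reached 7 and the highest other called 3, but 3 of the 7 calls rested on MIRI replicate 1. These counts argue against a random division of these libraries, with shares not adjusted over the comparisons. Chance between mice is not excluded, because the replicates may be technical. For MIRI+AICAR against MIRI, 10 of 56 splits called at least its 2 circRNAs, so chance was not excluded. The highest other called 16, several times the real count, by setting MIRI replicates 2 and 3 with MIRI+AICAR replicates 2, 3 and 4, which points to a structure of the samples other than the groups. The other side was MIRI replicate 1 with MIRI+AICAR replicates 1 and 5. It so held both libraries with high levels of circRNAs of Trpc6, Pde5a, Itgb3 and Med12l, and the cause was not tested. All 56 splits reached the 0 calls of MIRI+Compound C against Sham, and the highest other called 6. For MIRI against Sham, 10 splits are too few for a share under 0.05, and both the real and the highest other value were 2, reached by 2 splits. For the lists, MIRI against Sham again has too few splits (1 real, highest other 4, and 4 splits with as many). Chance was not excluded for the lists of MIRI+AICAR against MIRI (0 real, highest other 3, 56 of 56 splits), of MIRI+Compound C against MIRI (1 real, highest other 3, 20 of 56) or of MIRI+AICAR against MIRI+Compound C (5 real, highest other 5, 5 of 100).

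A hypothesis written before its test was that injury and the change from Compound C to AICAR move the same circRNAs, in a pair of comparisons with no library in common. Across 7917 circRNAs, which are not independent replicates, the log2 fold changes of MIRI against Sham and of MIRI+AICAR against MIRI+Compound C gave a Pearson r of 0.191 and a Spearman rho of 0.203. Simulated unchanged groups gave -0.04 to 0.03, and r was 0.307 in the upper part of expression. The simulated circRNAs varied independently, without the correlation that real libraries can carry, so this range is too narrow to judge r. Of the 44 circRNAs called between the drugs, 38 had the same sign in MIRI against Sham. A weak shared component is a possibility that this simulation cannot decide. A day or batch shared by Sham with MIRI+Compound C, which 0 labels give, could leave the same trace. Sham replicate 1 and MIRI+Compound C replicate 1 lay farthest out on the first principal component, the main axis of variation between libraries (-56.6 and -30.2). Their part in r was not tested.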
